A study of Arabidopsis thaliana with 4 samples.

How the data were processed

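The series measured RNA of Arabidopsis thaliana whole plants, 21 days old and untreated, on 4 Agilent 2-colour arrays. Of these, 2 arrays compared a line that overexpresses full-length cowpea VuDREB2A with wild type Col-0, and 2 compared a line that overexpresses a truncated form with wild type. Per the labels, the dyes were swapped within each line: replicate 1 carried the line in Cy3 and wild type in Cy5, and replicate 2 the reverse. Dye orientation and replicate number are therefore the same split of the arrays, called the replicate block here. The deposited design text counts 2 wild type replicates, so the lines may share wild type RNA of 1 replicate number.

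The authors scanned the arrays with Agilent Feature Extraction 10.7.3.1, per the file headers. Each deposited scanner file gives the median intensity of every spot and of its local background in both channels, the processed intensity after the software's background subtraction and dye normalization, and flags. The deposited LogRatio column is the log10 ratio of Cy5 over Cy3 processed signals. The table of deposited processed values holds log2 ratios of line over wild type. Regressed on the LogRatio column turned that way, its 4 columns had slopes from 0.998 to 1.00 across probes, and their medians were 0.01, -0.06, 0.04 and -0.07, so that scale, centring and direction are known. No file gives mean signals, so median signals replaced the mean signals that had been planned.

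Spots that the software marked as outliers were left out first (20 to 50 gene spots per array). Background was then corrected with normexp (offset 50) on median signal and median local background, log ratios were normalized within each array by loess with control spots at weight 0, and every ratio was turned to log2 of line over wild type. Leaving the marked spots out before the background correction, rather than after it, was decided after seeing the data. On full-length replicate 1, 5 neighbouring spots, all marked as background outliers, had a local background of at least 18652 in Cy3 (median over spots 40) and 4175 in Cy5 (45.5). With all spots in the fit, the modelled background SD was 539 in Cy3 and 250 in Cy5, against 2.11 and 1.86 without these 5. None of the alternatives runs the planned order. An alternative that keeps the marked spots throughout changes the count of genes called in the full-length line by over 1.5 times. Spots of 1 probe were averaged. Of the probes of a gene, the one with the highest mean intensity over the 4 arrays was used.

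A gene was tested if it was well above background in the line channel of both arrays of a line, or in the wild type channel of all 4 arrays. This left 22438 features of 43603 probes, after 86 probes with a missing array value were left out. Of these features, 20337 carried a locus identifier, and 20139 of those loci matched the table of current gene names. The other 2101 had no locus. Genes are named by that table, or by locus where it gives no symbol. The array's annotation is older than the table, so no coordinates are given.

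Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with both lines in 1 fit so that they share an estimate of the spread (2 residual and 3.18 prior degrees of freedom). Each line was tested against 0, and the lines against each other by the contrast truncated minus full-length. Every adjusted p is Benjamini-Hochberg adjusted, and the threshold is 0.05. Errors are SD over the 2 arrays of a line (n = 2), which differ in dye orientation as well as in replicate number. P-values of single genes therefore measure only the spread between these arrays, dye effects included. As far as the labels state, 1 line per construct was compared. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over 18 lists and 3 comparisons (54 tests). The test was repeated with the correlation estimated from the residuals. At the preset correlation camera takes its degrees of freedom from the number of genes, so list p-values do not measure spread between plants. With an estimated correlation it has only the residual ones (2, or 1 with the replicate block), at which hardly any list could pass over 54 tests. The set test fry was run as an alternative. On simulated data of 22438 genes, the fit recovered 86 of 100 genes changed by 1 log2 unit and 13 of 100 changed by 0.5, and called 6 unchanged genes. So few changed genes make the adjusted threshold stricter than in the data, where 15.5% and 13.2% of genes were called in the full-length and truncated line. The simulated rates therefore do not give the sensitivity in the data.

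Comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with 1 sign on both arrays (for the difference between lines, in both replicate pairs). It adds up to 4 members of each list with the largest mean log2 ratio in either line, and 10 genes known from work on DREB factors whatever their values: RD29A, RD29B, COR15A, KIN1, LEA14, GolS3, HSFA3, RAB18, DREB2A and CBF3. It names 108 distinct genes, and CBF3, below the filter, is not among them. The top lists passed over probes with no named gene. The 18 lists cover DRE-driven stress genes, LEA proteins and osmoprotectant synthesis, heat shock proteins and factors, ABA-responsive genes, DREB-type AP2/ERF factors, salicylic acid and defence genes, jasmonate and ethylene defence genes, flavonoid and anthocyanin synthesis, photosynthesis, gibberellin metabolism and growth, oxidative stress and detoxification, senescence and sugar starvation, root markers, flowering and floral organ markers, seed storage markers, morning clock genes, evening clock genes and reference genes.

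A probe not well above background on any array of a group has only a bound there. The brighter group's mean is then set against, per array, the higher of the dim probe's own signal and the lowest signal among probes well above background, after loess and Aquantile normalization. Alternatives changed the background correction, the signal used, the normalization, the filter, the probe rule, the variance prior, the set test and the arrays included. They also added a dye term, which equals the replicate block. It was kept out of the main fit because it also removes the spread between replicates if the lines share wild type RNA. After it, the SD between replicates of 50 probes on 5 spots each was 0.0559, beside 0.0556 from spot noise. P-values with the replicate block therefore measure little beyond spot noise. The simulated overlap of calls was added after seeing the data. All 4 arrays lie on 1 slide, so slide could not be fitted as a block. A planned search for the DRE motif in promoters was not run, and a genome sequence was not used here. Python 3.11.15 and matplotlib 3.10.9 drew the plots.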

Results

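Transcript levels were measured in 21-day-old whole plants grown on sucrose-containing agar without stress treatment. VuDREB2A is a cowpea transcription factor of the DREB2 type, a class known to bind the dehydration-responsive element (DRE) of stress genes. Both the full-length and the truncated form were driven by the 35S promoter, and each line was hybridised against wild type on 2 arrays with swapped dyes. On each array 43603 probes were read, 0 gene spots were saturated, and 65.6% to 72.5% of probes were well above background in a channel. The number of arrays (2 per line) limits the precision. No probe on the array is named for the cowpea transgene, so its level was not measured. The native DREB2A gene had a log2 ratio of 0.38 ± 0.21 (SD, n = 2) in the full-length line and 0.13 ± 0.13 in the truncated line. Neither passed the threshold (adjusted p = 0.0535 and 0.409) except with the replicate block in the fit (adjusted p = 0.000284 and 0.0247). The block removes the spread that replicates of both lines share, so its p-values, here and below, measure little beyond spot noise. Another DREB2A probe gave 0.11 in the full-length and 0.11 in the truncated line.

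The comparison of the full-length line with wild type asks which genes the unmodified factor changes in unstressed plants. SAG13, a senescence-associated dehydrogenase gene, was 8.25-fold higher (log2 ratio 3.04 ± 0.42, SD, n = 2; adjusted p = 0.003), although wild type was well above background on only 1 of its 2 arrays. PAD3, which encodes the last enzyme of camalexin synthesis, was 3.89-fold higher (1.96 ± 0.33), HR4, a gene of the RPW8 resistance family, 4.12-fold (2.04 ± 0.15), and CORI3, a coronatine-induced cystine lyase gene, 4.37-fold (2.13 ± 0.01). AT1G02470 (2.45 ± 0.07), the thioredoxin gene TH8 (2.35 ± 0.31), AT4G12490 (2.1 ± 0.09), AT1G27020 (2.04 ± 0.04), the defensin gene PDF1.2c (1.99 ± 0.01) and AT5G44575 (1.97 ± 0.24) completed the 10 largest rises. Among features with a locus, falls were smaller: AT1G66100 fell most (-1.62 ± 0.09), followed by BT2, a BTB and TAZ domain gene (-1.26 ± 0.04), the transcription factor gene WRKY40 (-1.20 ± 0.20), and 7 others from -1.13 to -1.08. Another 4 features with no locus ranked among these falls and were passed over.

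Heat shock genes rose in the full-length line. Of 28 tested members of that list, 18 were higher, 0 lower and 10 not past the threshold (19 and 0 adjusted over the list alone), with a median log2 ratio of 0.79. HSP90.1, a chaperone gene, was 3.01-fold higher (1.59 ± 0.04), and the small heat shock protein genes AT1G07400 and AT1G53540 were higher by 1.83 ± 0.07 and 1.14 ± 0.12. The list shift passed camera at the preset correlation (adjusted p = 8.32e-11) but not with an estimated correlation (adjusted p = 0.358). The value was 0.358 or higher for each of the 15 list shifts that passed, so none of the calls held with it. With 2 residual degrees of freedom hardly any list could pass that test, so it cannot decide for or against a shift. All 15 passed with the replicate block at the preset correlation. The heat shock median was 0.75 and 0.77 on the arrays of replicates 1 and 2. HSFA3, a heat shock factor gene known as a target of DREB2A, had a log2 ratio of -0.08 ± 0.15 (adjusted p = 0.539, and adjusted p = 0.0698 with the replicate block).

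Jasmonate and ethylene defence genes also shifted up in the full-length line, with 10 of 18 higher and 2 lower (10 and 4 adjusted over the list alone; median 0.38; adjusted p = 0.00233, and adjusted p = 0.476 with an estimated correlation). The plant defensin genes PDF1.2c and PDF1.3 were higher by 1.99 ± 0.01 and 1.84 ± 0.05, whereas the vegetative storage protein genes VSP1 and VSP2 were lower (-0.61 ± 0.09 and -0.58 ± 0.05). In the oxidative stress and detoxification list 8 of 21 genes were higher and 3 lower (13 and 3 adjusted over the list alone; median 0.23; adjusted p = 0.0052, and adjusted p = 0.514 with an estimated correlation). The glutathione transferase genes GSTF6 (1.83 ± 0.07) and GSTU4 (1.2 ± 0.03) were among them. With median centring in place of loess, this list's median was -0.06 and its shift did not pass (adjusted p = 0.12). Flavonoid and anthocyanin genes rose for 8 of 17 members, with 0 lower (9 and 0 adjusted over the list alone; median 0.31; adjusted p = 0.000644, and adjusted p = 0.476 with an estimated correlation). Among the morning clock genes 4 of 9 were higher and 1 lower (5 and 1 adjusted over the list alone; median 0.27; adjusted p = 0.0172, and adjusted p = 0.514 with an estimated correlation), led by LNK2 (0.81 ± 0.01). With median centring the morning clock shift did not pass (adjusted p = 0.12).

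Photosynthesis and root genes were lower in the full-length line. Of 34 photosynthesis genes 7 were lower and 0 higher (8 and 0 adjusted over the list alone; median -0.24; adjusted p = 3.59e-05, and adjusted p = 0.633 with an estimated correlation), such as the photosystem I genes PSAH2 (-0.51 ± 0.14) and PSAG (-0.46 ± 0.00). The list's median differed between the arrays, at -0.45 on replicate 1 and -0.09 on replicate 2, and without full-length replicate 1 the shift did not pass (adjusted p = 0.131), nor did it with the set test fry (adjusted p = 0.381). Of these 34 genes, 31 were among the brightest 1% of genes. Of 21 root markers 7 were lower and 0 higher (11 lower and 3 higher adjusted over the list alone; median -0.21; adjusted p = 0.00728, and adjusted p = 0.594 with an estimated correlation). The aquaporin gene TIP2;3 (-0.76 ± 0.25) was among the lower ones. This root marker shift (median -0.21) accompanied every gene group described for this line.

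Genes that carry the DRE or follow active DREB2A showed no common shift in the full-length line. Of 22 tested, 3 were higher, 3 lower and 16 not past the threshold (4 and 3 adjusted over the list alone; median 0.01; adjusted p = 0.912). LEA14 (0.38 ± 0.03, adjusted p = 0.0187) and GolS3 (0.29 ± 0.01, adjusted p = 0.0298) were higher, and each call was lost without either full-length replicate (0.36 and 0.41 for LEA14, 0.28 and 0.29 for GolS3). RD29A had 0.22 ± 0.15, KIN1 0.21 ± 0.04, COR15A -0.17 ± 0.00, RAB18 -0.32 ± 0.16 and RD29B 0.00 ± 0.08, none past the threshold. With the replicate block in the fit, RD29A (adjusted p = 0.0119), KIN1 (adjusted p = 0.00298), COR15A (adjusted p = 0.00915) and RAB18 (adjusted p = 0.000417) passed, and RD29B did not (adjusted p = 0.999). CBF3 was below the filter and was not tested. The lists of LEA proteins (3 of 19 higher, 1 lower), ABA-responsive genes (4 of 22 higher, 1 lower), DREB-type factors (0 of 12 higher, 3 lower), salicylic acid genes (2 of 17 higher, 1 lower), gibberellin genes (2 of 17 higher, 2 lower), senescence genes (4 of 14 higher, 5 lower), floral genes (1 of 11 higher, 3 lower), evening clock genes (0 of 10 higher, 1 lower) and reference genes (1 of 13 higher, 2 lower) did not shift (adjusted p from 0.299 to 0.884). Adjusted over the list alone, these counts were 3 and 2, 5 and 4, 2 and 4, 2 and 2, 3 and 4, 4 and 5, 1 and 3, 0 and 1, and 1 and 2. Under fry, however, evening clock genes passed as lower (adjusted p = 0.0421) and reference genes as higher (adjusted p = 0.019). The 1 seed storage gene measured, CRA1, had 0.10 ± 0.08. The reference gene GAPC1 was higher by 0.93 ± 0.03 at its brightest probe, while its 3 other probes gave 0.06, -0.12 and -0.02.

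In all, 2111 genes were higher and 1378 lower in the full-length line (3489 of 22438, 15.5%, limma), 108 and 23 of them at least 2-fold. With outlier-marked spots kept throughout, which is not the planned order, 1018 genes passed. SAG13 (2.01, adjusted p = 0.105), PAD3 (1.07, adjusted p = 0.0915), PDF1.2A (0.49, adjusted p = 0.195), PDF1.2b (0.89, adjusted p = 0.134), AT1G53540 (0.76, adjusted p = 0.0984) and GSTU4 (0.71, adjusted p = 0.12) were then among the genes no longer called. The count was 1773 without full-length replicate 1, 1819 without replicate 2, 1033 with no filter on dim probes, 9 with median centring and 12751 with the replicate block in the fit. Median centring ended 173 of the 205 calls of named genes over the 3 comparisons, and turned the direction of none.

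The comparison of the truncated line with wild type asks which genes the shortened factor changes. The 4 plant defensin genes of the PDF1 family rose most: PDF1.2c was 18-fold higher (4.17 ± 0.02, SD, n = 2; adjusted p = 9.5e-05), PDF1.3 15.9-fold (3.99 ± 0.06), PDF1.2b 15.4-fold (3.95 ± 0.26) and PDF1.2A 14.4-fold (3.84 ± 0.23). Their sequences are close to identical, so signal may be shared between their probes. AT2G30766 (2.55 ± 0.45), AT1G47400 (2.39 ± 0.06), AT2G14247 (2.34 ± 0.13) and AT1G47395 (2.21 ± 0.21) followed. The root iron transporter gene IRT1 was 4.57-fold higher (2.19 ± 0.05), and PAP1, a MYB regulator of anthocyanin synthesis, 4.42-fold (2.14 ± 0.18). Outside the 10 largest rises, the ferric reductase gene FRO2, also of iron uptake, was 4.14-fold higher (2.05 ± 0.04). The largest falls were in AT1G52820 (-2.73 ± 0.10), the cytochrome P450 gene CYP712A1 (-2.71 ± 0.06), AT4G14060 (-2.60 ± 0.24), VSP2 (-2.22 ± 0.07) and VSP1 (-2.16 ± 0.08). MLP328 (-2.01 ± 0.41), AT5G37990 (-1.90 ± 0.07), AT5G37970 (-1.74 ± 0.10), AT3G62550 (-1.73 ± 0.14) and the sugar transporter gene SWEET10 (-1.73 ± 0.01) completed the 10 largest falls. Other probes of VSP1 gave -1.06, -1.13 and -2.27.

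Flavonoid and anthocyanin genes rose together in the truncated line: 15 of 17 were higher and 0 lower (16 and 0 adjusted over the list alone; median 0.68; adjusted p = 4.71e-12, and adjusted p = 0.358 with an estimated correlation). DFR, an enzyme gene of anthocyanin synthesis, was 2.79-fold higher (1.48 ± 0.10), TT19, a glutathione transferase gene needed for anthocyanin storage, 2.38-fold (1.25 ± 0.04; 0.51 at its other probe), and F3H 2.04-fold (1.03 ± 0.08). Heat shock genes were higher for 16 of 28 members and lower for 3 (18 and 4 adjusted over the list alone; median 0.81; adjusted p = 1.24e-07, and adjusted p = 0.358 with an estimated correlation). AT1G53540 was 4.41-fold higher (2.14 ± 0.07), AT1G07400 3.59-fold (1.84 ± 0.03), HSP90.1 3.47-fold (1.80 ± 0.06) and HSP17.6II 3.25-fold (1.70 ± 0.00). The 3 lower members were GolS1 (-0.84 ± 0.06), HSFA7A (-0.41) and HSP18.2 (-0.28), the last 2 named after their values were seen. HSFA3 had -0.24 ± 0.15 (adjusted p = 0.131, and adjusted p = 0.00147 with the replicate block).

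Jasmonate and ethylene defence genes in the truncated line went both ways, with 9 of 18 higher and 2 lower (12 and 3 adjusted over the list alone; median 0.32; adjusted p = 0.00022, and adjusted p = 0.476 with an estimated correlation). Defensin genes rose, and VSP1 and VSP2 fell. ABA-responsive genes had a median of 0.14 with 3 of 22 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0176, and adjusted p = 0.514 with an estimated correlation). RD20, a caleosin gene, was higher by 0.90 ± 0.01. The ABA shift did not pass without truncated replicate 2 (adjusted p = 0.0916) or with Agilent's own log ratios (adjusted p = 0.0532). Photosynthesis genes had a median of -0.12 with 1 of 34 lower, PSAG (-0.27 ± 0.04; not past the threshold without either truncated replicate), and 0 higher (0 and 0 adjusted over the list alone; adjusted p = 0.0176, and adjusted p = 0.742 with an estimated correlation). Their median was -0.37 on replicate 1 and 0.03 on replicate 2, so that the direction turned without truncated replicate 1 (0.03, adjusted p = 0.791). With fry this shift did not pass (adjusted p = 0.721).

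DRE-driven genes did not shift as a list in the truncated line, with 2 of 22 higher and 5 lower (2 and 6 adjusted over the list alone; median -0.06; adjusted p = 0.45). RD29A (0.52 ± 0.06, adjusted p = 0.0183) and COR15A (0.42 ± 0.09, adjusted p = 0.0187) were the 2 that rose, and COR15A did not pass without truncated replicate 1 (0.36, adjusted p = 0.106). COR413IM1 (-1.09 ± 0.13) and the dehydrin gene LTI30 (-0.64 ± 0.17) fell. RD29B (0.14 ± 0.12), KIN1 (0.18 ± 0.02), LEA14 (-0.11 ± 0.07), GolS3 (0.03 ± 0.01) and RAB18 (-0.23 ± 0.14) did not pass. With the replicate block KIN1 (adjusted p = 0.00556), LEA14 (adjusted p = 0.0379) and RAB18 (adjusted p = 0.00178) passed, and RD29B (adjusted p = 0.0587) and GolS3 (adjusted p = 0.441) did not. Other probes of RAB18 gave 0.10 and 0.22 in the truncated line, opposite in sign to the probe used. No shift passed for LEA proteins (2 of 19 higher, 4 lower), DREB-type factors (1 of 12 higher, 3 lower), salicylic acid genes (1 of 17 higher, 2 lower), gibberellin genes (2 of 17 higher, 4 lower), oxidative stress genes (3 of 21 higher, 1 lower), senescence genes (1 of 14 higher, 6 lower), floral genes (2 of 11 higher, 4 lower), morning clock genes (2 of 9 higher, 0 lower), evening clock genes (0 of 10 higher, 2 lower) and reference genes (1 of 13 higher, 1 lower; adjusted p from 0.0991 to 0.743). Adjusted over the list alone, these counts were 2 and 5, 2 and 3, 1 and 2, 3 and 4, 5 and 2, 3 and 7, 2 and 4, 2 and 1, 0 and 2, and 1 and 1. Under fry, however, senescence genes (adjusted p = 0.0177) and evening clock genes (adjusted p = 0.0177) passed as lower. Root markers had a median of -0.03 (adjusted p = 0.912), and the 2 that rose were IRT1 and FRO2. The seed gene CRA1 had -0.06 ± 0.09.

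In all, 1591 genes were higher and 1381 lower in the truncated line (2972 of 22438, 13.2%, limma), 62 and 54 of them at least 2-fold. The count was 1325 without truncated replicate 1, 1624 without replicate 2, 704 with no filter on dim probes, 40 with median centring and 12171 with the replicate block.

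The contrast of the lines asks which genes differ between them. With 1 line per construct, as far as the labels state, it cannot tell truncation from other differences between the lines, such as transgene level. The truncated line exceeded the full-length line most for PDF1.2A (difference of log2 ratios 3.11, SE 0.16; adjusted p = 0.00472), AT2G14247 (2.85), AT2G30766 (2.81), AT1G47400 (2.6), PDF1.2b (2.53), AT1G47395 (2.47), IRT1 (2.35, SE 0.21) and PAP1 (2.19, SE 0.12). NAS3, a nicotianamine synthase gene, rose in the full-length line (1.63 ± 0.04) and fell in the truncated line (-1.31 ± 0.01), a difference of -2.94 (SE 0.08; adjusted p = 0.00322). AT1G27020 (-2.70), AT4G12490 (-2.60), AT1G02470 (-2.42), TH8 (-2.30) and HR4 (-2.22) were also higher in the full-length line than in the truncated one. SAG13 differed too (adjusted p = 0.0139), but on the truncated arrays its wild type was not well above background on either and the line on only 1 of 2, so no exact difference is ranked. With outlier-marked spots kept throughout, 20 of the 57 differences of named genes were no longer called, among them SAG13 (-1.81, adjusted p = 0.318), TH8 (-1.50, adjusted p = 0.109) and AT1G02470 (-1.80, adjusted p = 0.0645). With Agilent's log ratios 27 were not called, including SAG13 (-4.76, adjusted p = 0.143), IRT1 (3.46, adjusted p = 0.073) and PDF1.2A (2.91, adjusted p = 0.0512). FRK1, a kinase gene induced in defence, was not well above background in the truncated line. Channel intensities, compared directly between the lines, put it at least 2.98-fold higher in the full-length line. The fit, which compares ratios to wild type, gave a difference of 2.86-fold (adjusted p = 0.0109), and did not call it with outlier-marked spots kept (-0.88, adjusted p = 0.257).

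Among the lists, flavonoid genes were higher in the truncated than in the full-length line (5 of 17 higher, 0 lower; 9 and 1 adjusted over the list alone; median difference 0.42; adjusted p = 1.24e-07, and adjusted p = 0.358 with an estimated correlation). Root markers also differed (2 of 21 higher, 0 lower; 9 and 2 adjusted over the list alone; 0.26; adjusted p = 0.000599, and adjusted p = 0.562 with an estimated correlation). Oxidative stress genes were lower (0 of 21 higher, 4 lower; 2 and 7 adjusted over the list alone; -0.14; adjusted p = 0.0241, and adjusted p = 0.562 with an estimated correlation), a shift that did not pass without truncated replicate 2 (adjusted p = 0.0549) or with median centring (adjusted p = 0.12). Heat shock genes (median difference 0.09; adjusted p = 0.299), jasmonate and ethylene genes (0.18; 0.395) and DRE-driven genes (-0.08; 0.339) did not differ as lists past the threshold. Photosynthesis genes (0.10; adjusted p = 0.0513) passed with the replicate block (adjusted p = 0.000793), but not with the block and an estimated correlation (adjusted p = 0.733) or with fry (adjusted p = 0.767), and their median ran from -0.11 to 0.28 with 1 array left out. The other 11 lists did not differ with camera (adjusted p from 0.0845 to 0.98). Under fry, senescence (adjusted p = 0.0315), morning clock (adjusted p = 0.0399) and reference genes (adjusted p = 0.0421) were lower in the truncated line. Jasmonate and ethylene genes were higher there (fry adjusted p = 0.0418). A list's median, mean and test differed in sign for senescence, salicylic acid and floral genes in the full-length line, for root markers and DREB-type factors in the truncated line, and for salicylic acid genes in the contrast, none of them past the threshold. In all, 218 genes were higher and 483 lower in the truncated line than in the full-length line (701, 3.12%, limma), with 86 in total without a filter on dim probes, 164 with Agilent's log ratios, 367 with outlier-marked spots kept and 8782 with the replicate block. With median centring limma called 0, with 399 genes at an unadjusted p under 0.05.

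Calls overlapped between the lines: 687 genes were higher in both, against 150 expected from independent calls, and 474 were lower in both, against 84.8. Opposite calls numbered 132, against 228 expected. These expected counts leave out wild type RNA that the lines may share. In 100 simulations with no effect and shared wild type RNA, limma called 0 genes in both lines, and lists as long as the real ones, ranked by t, had 606 genes higher in both on average (highest 657), 421 lower in both (highest 461) and 45.6 opposite (highest 66). The 0 calls follow from simulating no effect. The simulation split the spread equally between line and wild type RNA and held no dye or replicate term. In the data, the deviations of replicate 1 from replicate 2 correlated between the lines at r = 0.775. Part of the overlap may come from shared wild type RNA, but the simulation cannot size that part. Across genes, which are not independent replicates, the mean log2 ratios correlated at r = 0.445 with a covariance of 0.0271. With no effect and shared wild type RNA (100 simulations), r was 0.5, which the equal split fixes, and the covariance 0.00349. Pairs of arrays that share neither replicate number nor dye orientation gave r = 0.271 and 0.268, with covariances of 0.019 and 0.0193. At least 2-fold on both arrays of a line were 88 genes higher and 14 lower in the full-length line, and 50 higher and 45 lower in the truncated line. In each line 0 genes were 2-fold in opposite directions on the 2 arrays.

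**Figure D1:**
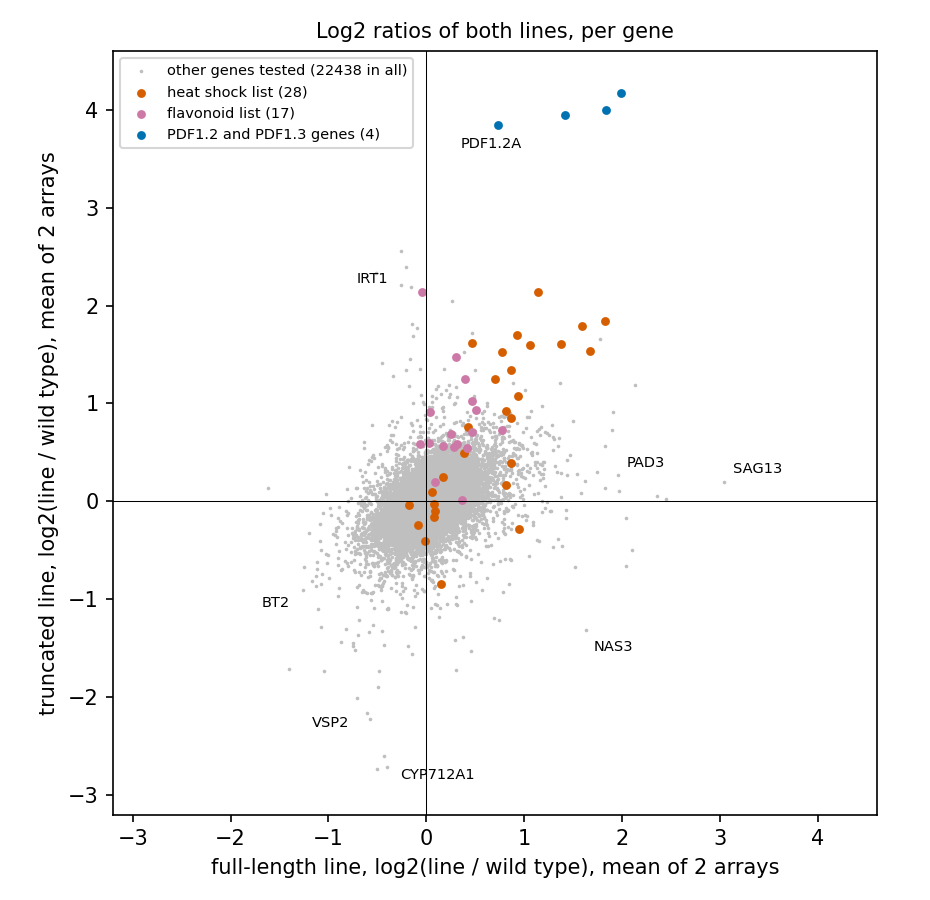
Mean log2 ratio of line over wild type for each of 22438 genes, with the full-length line on the horizontal and the truncated line on the vertical axis (2 arrays each); colours mark the heat shock list (28), the flavonoid list (17) and 4 PDF1.2 and PDF1.3 genes. The defensin genes lie from 3.84 to 4.17 in the truncated line, and SAG13 lies at 3.04 in the full-length line.

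**Figure D2:**
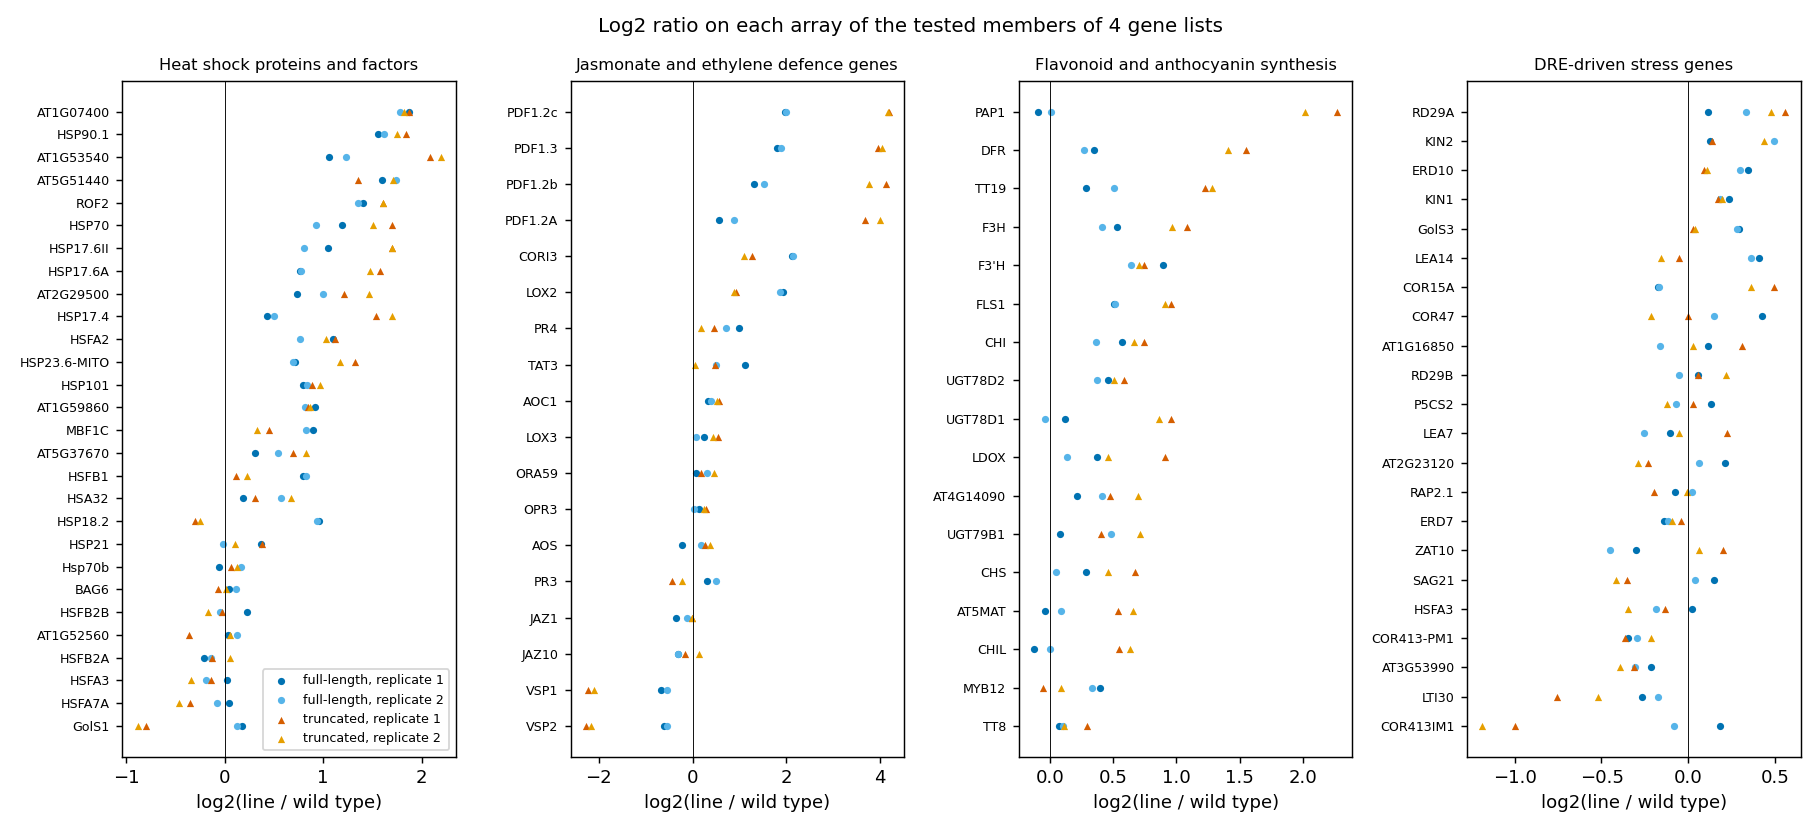
Log2 ratio of line over wild type on each of the 4 arrays (1 symbol per array) for the tested members of 4 gene lists, 1 row per gene. Heat shock genes have medians of 0.79 and 0.81 in the full-length and truncated line, and DRE-driven genes 0.01 and -0.06.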

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

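The tests of dye bias, of shared wild type RNA, of HSFA3, of the share of root and of a single defensin transcript were chosen only after the result was seen. The tests of iron deficiency and iron sufficiency genes used genes whose values had not been looked at when the tests were set.

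Each value here was singled out because the 2 lines differed from each other by limma's test of the difference. That test cannot tell the constructs apart from other differences between the lines. The number of genes that differed was 701, and 3 lists differed: flavonoid genes (median difference, truncated minus full-length, 0.42), root markers (0.26) and oxidative stress genes (-0.14). Of the named genes 57 differed, 22 higher and 35 lower in the truncated line, and 7 were called in opposite directions in the 2 lines.

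Higher in the truncated line, as differences of log2 ratios, were the defensin genes PDF1.2A (3.11), PDF1.2b (2.53), PDF1.2c (2.19) and PDF1.3 (2.16). AT2G14247 (2.85), AT2G30766 (2.81), AT1G47400 (2.6), AT1G47395 (2.47), IRT1 (2.35) and FRO2 (1.79) were higher too. The flavonoid genes PAP1 (2.19), DFR (1.17) and TT19 (0.86) and the heat shock genes AT1G53540 (1.00) and HSP17.6II (0.78) followed. The other TT19 probe gave closer log2 ratios, 0.35 in the full-length and 0.51 in the truncated line. The rest were AT1G66100 (1.75), WRKY40 (0.88), AT5G62280 (0.85), WRKY33 (0.83), PI (0.77), GA2OX2 (0.67) and COR15A (0.60).

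Lower in the truncated line were NAS3 (-2.94), AT1G27020 (-2.70), AT4G12490 (-2.60), AT1G02470 (-2.42), CYP712A1 (-2.31), TH8 (-2.30), AT1G52820 (-2.22), HR4 (-2.22), AT4G19430 (-2.19), AT4G14060 (-2.16), SWEET10 (-2.03), AT5G44575 (-1.87), PAD3 (-1.69), VSP2 (-1.64) and VSP1 (-1.55). Smaller differences were those of AT5G37990 (-1.41), SEP3 (-1.33), GSTF6 (-1.27), AT5G37970 (-1.25), COR413IM1 (-1.14), GSTF7 (-1.10), DIN2 (-1.09), GolS1 (-0.99), CORI3 (-0.94), M17 (-0.87), GSTU4 (-0.80), GA2OX1 (-0.77), ASN1 (-0.70), GASA6 (-0.69), AT3G62550 (-0.68), SWEET15 (-0.68), LNK2 (-0.52) and GAPC1 (-0.50). FRK1 (-1.51) was not well above background in the line on either truncated array, and SAG13 (-2.84) not in wild type on either and in the line on only 1 of 2, so these 2 values are not exact differences. With outlier-marked spots kept 20 of the 57 differences were not called, with Agilent's log ratios 27, with no filter on dim probes 29 and with median centring 57. Without 1 array the difference no longer passed for COR15A, GAPC1 and LNK2 (several arrays in turn), GA2OX2 (truncated replicate 2; 0.56, adjusted p = 0.0584), AT3G62550 (truncated replicate 1; -0.58, adjusted p = 0.0549) and SWEET15 (full-length replicate 1; -0.59, adjusted p = 0.0519). For COR15A these were both full-length replicates and truncated replicate 1 (0.53 to 0.60, adjusted p from 0.0523 to 0.0758), for GAPC1 each of the 4 (-0.52 to -0.47, adjusted p from 0.0783 to 0.122) and for LNK2 each of the 4 (-0.53 to -0.51, adjusted p from 0.0725 to 0.1). The 3 other probes of GAPC1 gave 0.06, -0.12 and -0.02 in the full-length line and 0.13, 0.02 and -0.03 in the truncated line. Other probes of VSP1 gave -0.56, -0.70 and -0.97 in the full-length line and, in the same order, -1.06, -1.13 and -2.27 in the truncated line.

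Heat shock genes were higher in both lines. Dye bias is excluded, since the list's median was at least 0.75 on each of the 4 arrays, whichever dye the line carried. A low level in wild type RNA shared by both lines cannot give the differences between the lines, seen for 7 of the 28 members. Of these, 4 were higher and 3 lower in the truncated line. As a whole the list did not differ between the lines (median difference 0.09, camera adjusted p = 0.299). For the rise common to both lines, low shared wild type RNA cannot be told apart from an effect of the factor. Whether wild type RNA was shared is not stated, every array sets a line against wild type, and with medians of 0.75, 0.77, 0.77 and 0.85 both wild type replicates would have to be low. A rise of the HSFA3 transcript is argued against by its upper 95% bound, 0.131 on the log2 scale at most, while an effect of the transgene, whose transcript was not measured, stays open as a hypothesis.

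Iron deficiency genes were higher in the truncated line, with 11 genes that drew attention at a median log2 ratio of 1.81, from 1.17 to 2.55. Dye bias is excluded by the lower of the medians on the 2 truncated arrays (1.81), and a larger share of root by the other 19 root markers, whose median was -0.0368 (from -0.32 to 0.26). A response of the group was tested on 17 other iron deficiency genes, of which 10 rose and 0 fell (median 0.53; adjusted p = 9.57e-07, and adjusted p = 0.101 with an estimated correlation). Low iron status remains open: 9 iron sufficiency genes had a median of -0.08 (adjusted p = 0.276), 1 higher and 1 lower. A response of these genes to the truncated factor may be biological, as a hypothesis found and tested on the same data.

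The 4 plant defensin genes were higher in both lines and more so in the truncated line. Dye bias is excluded, since the lowest of their log2 ratios on the 4 arrays was 0.57. A single transcript read by all 4 probes stays open: their log2 ratios spanned 1.26 in the full-length line (SE 0.127) but 0.33 in the truncated line. Elsewhere among the named genes, the probe used differed from another probe of its gene by up to 1.1. Part of the rise common to both lines may come from shared wild type RNA, which was not tested for these genes. The difference between the lines does not rest on it if the wild type RNA was shared.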

How the results depend on the processing

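The settings that keep feature-marked spots, and that join the replicate block to an estimated correlation, were chosen after seeing the data. So was the main order of marking and background correction. Signal over background limits the calls: 65.6% to 72.5% of probes were well above background in a channel.

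The replicate block (dye term, 1 residual degree of freedom) called 12751 genes in the full-length line, 12171 in the truncated line and 8782 between the lines. By design it leaves the fitted log2 ratios unchanged, so no direction could turn. It kept the calls made without it, which adds no support for them, since it removes the spread that the lines share. Median centring called 9 genes, 40 genes and, between the lines, 0 (limma; 1327, 890 and 399 at an unadjusted p under 0.05). Without a filter on dim probes, which adds genes to the test (34127 in all), 1033, 704 and 86 passed. With outlier-marked spots kept, 1018 passed in the full-length line, 2672 in the truncated line and 367 between the lines, and with background-marked spots alone left out 3487, 2971 and 699. On full-length replicate 1, 5 marked spots raise the modelled background SD from 2.11 to 539 (Cy3) and from 1.86 to 250 (Cy5). Between the lines, an offset of 10 gave 316, Agilent's log ratios 164, the deposited log2 ratios 173, and an intensity trend with a robust prior 1108. Apart from the explained ones, the cause was not tested. The other alternatives stayed within 1.5 times of each count. Leaving out 1 array, a lone array being assumed to vary like the other line's, gave 1773 to 4308 genes in the full-length line, 1325 to 3553 in the truncated line and 713 to 801 between the lines. The genes at least 2-fold on both arrays numbered 254 (Agilent's log ratios), 253 (deposited), 59 (median centring), 538 (1.5-fold) and 21 (3-fold) in the full-length line, and 218, 219, 423 (1.5-fold) and 32 (3-fold) in the truncated line, median centring staying within 1.5 times there. The correlation between the lines was 0.402 to 0.423 with 1 array left out, and 0.271 and 0.268 for the cross pairs.

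Of the 54 list tests 15 passed at the preset correlation. Camera with an estimated correlation had 2 residual degrees of freedom, and 1 with the replicate block, at which hardly any test could pass. With an estimated correlation 0 did (camera; lowest adjusted p = 0.358; 5 at an unadjusted p under 0.05), with the replicate block 16, with both 0 (lowest adjusted p = 0.733; 0 unadjusted), with fry 21, and with 1 array left out 14 to 18. Photosynthesis genes in the truncated line turned direction without truncated replicate 1 (median 0.032), against -0.37 without replicate 2. Of 205 calls of named genes, median centring ended 173, no filter 70, outlier-marked spots kept 61, Agilent's log ratios 40, the deposited log2 ratios 39, an offset of 10 24, leaving out 1 array 15 to 21, and each other alternative at most 6, with 0 reversed. The DRE motif alternatives were not run, since a genome was not used here, and a slide or scan block could not be fitted, since all arrays share 1 slide.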

Other observations

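The tests of phosphate starvation, sugar-repressed and touch and elicitor genes were chosen only after a few genes of each kind had been seen to change. They used other genes, whose values had not been looked at. With the iron lists, 5 lists in 3 comparisons were tested (15 tests, camera).

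Phosphate starvation genes were higher in the truncated line. The phosphatase gene AT1G73010 (symbol PS2; 1.53) and the galactolipid synthase gene MGDC (1.34) drew attention. Of 14 other genes of that response 11 rose and 0 fell (median 0.51), among them the sulfolipid synthesis genes SQD1 (0.78) and SQD2 (0.57), the galactolipid gene MGD2 (0.68) and the signalling gene SPX1 (0.72). A response as a group is a candidate explanation (adjusted p = 1.18e-08, and adjusted p = 0.101 with an estimated correlation). In the full-length line 4 were higher and 3 lower (adjusted p = 0.594), and the lines differed (median difference 0.29; adjusted p = 0.000874, and adjusted p = 0.166 with an estimated correlation).

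Sugar-repressed genes were lower in both lines. ASN1 (-0.75 and -1.44 in the full-length and truncated line), DIN1 (-0.60 and -0.46), DIN10 (-0.61 and -0.47) and BT2 (-1.26 and -0.91) drew attention. Of 16 other genes that sugar is known to repress, 9 fell in the full-length and 11 in the truncated line, and 0 rose in either (medians -0.37 and -0.37), including the sugar transporter gene STP1 (-0.66 and -0.92) and DYL1 (-0.55 and -0.93). A fall as a group may be common to both lines (larger adjusted p = 9.57e-07, and adjusted p = 0.101 with an estimated correlation), and low sugar status of shared wild type plants was not tested. The lines did not differ past the threshold (adjusted p = 0.0718). DIN2 went the other way in the full-length line (1.38, adjusted p = 0.0047; 0.29 in the truncated line). The planned list of senescence and sugar starvation genes, which holds DIN2, had 4 of 14 higher and 5 lower in the full-length line (camera adjusted p = 0.626). In the truncated line 1 was higher and 6 lower (camera adjusted p = 0.182). The list did not shift with camera, while with fry it was lower in the truncated line (adjusted p = 0.0177) but not in the full-length line (adjusted p = 0.208).

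Touch and elicitor early genes were lower in the full-length line. TCH4 (-0.93), WRKY33 (-0.97), WRKY40 (-1.20) and ERF6 (-1.03) drew attention. Of 18 other early genes 7 fell and 0 rose, among them TCH3 (-0.77) and SZF1 (-0.86), with a median of -0.26. A fall as a group is a candidate explanation (adjusted p = 0.000874, and adjusted p = 0.155 with an estimated correlation). In the truncated line 1 was higher and 1 lower (adjusted p = 0.2), and the lines differed (median difference 0.21; adjusted p = 0.00597, and adjusted p = 0.166 with an estimated correlation). Handling at harvest moves such genes within minutes and was not recorded.

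In the full-length line, 17 iron deficiency genes had a median of -0.01 (adjusted p = 0.93), with 4 higher and 1 lower. The 4 were FRO3 (0.58), NAS1 (0.94), NAS2 (0.35) and OPT3 (0.41), which also rose in the truncated line (0.63, 0.30, 0.53 and 0.92). The 9 iron sufficiency genes had a median of -0.04 (adjusted p = 0.994), with 2 higher and 1 lower. Of the deficiency genes, 5 were higher in the truncated than in the full-length line and 1 was lower, NAS1 (-0.63). Between the lines the deficiency genes differed by 0.29 (adjusted p = 9.57e-07, and adjusted p = 0.101 with an estimated correlation) and the sufficiency genes by -0.19 (adjusted p = 0.113). Root markers differed between the lines by a similar amount (0.26, adjusted p = 0.000599, and adjusted p = 0.562 with an estimated correlation), and the 19 outside the iron genes had medians of -0.23 in the full-length and -0.04 in the truncated line. A different share of root was not tested for this difference between the lines.

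The deviations of replicate 1 from replicate 2 correlated between the lines at r = 0.775 across genes. For 50 probes on 5 spots each, the SD of single spots within an array was 0.113 to 0.138. The SD between replicates was 0.158 in the full-length and 0.179 in the truncated line, and 0.0559 after the replicate block was removed, beside 0.0556 for a 5-spot mean from spot noise.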
